A study of Homo sapiens with 3 samples.

How the data were processed

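DDX6 eCLIP was performed on MOLM-13 acute myeloid leukaemia cells, per the labels' protocols: cells were cross-linked with ultraviolet light and lysed, RNA was trimmed with RNase I, DDX6 was immunoprecipitated, and RNA from the complexes was made into libraries after gel separation. The series has 2 IP libraries and 1 input library, and the labels give the replicate number of each IP. Per the submitters' processing notes, UMI-tools, cutadapt, STAR and SAMtools were used with genome build hg19. Their versions, the peak caller, the counter, the gene annotation and the way the counting treated strand are not given in the sources used here.

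The authors deposited raw read counts per gene and transcript region for each library, with 1 line of column totals and 1 line of intergenic reads. Both lines were left out of the tests and of the library sizes in the main fits. Shares of reads, ratios of tRNA reads and the alternative of scaling to library size alone used all counted reads, intronic and intergenic ones included. As exonic reads took a larger share of the IP libraries, that alternative raises exonic folds. Intergenic reads made up 4.05%, 3.78% and 2.63% of IP replicate 1, IP replicate 2 and the input. The authors' deposited peak lists, 1 per IP library, give each peak a -log10 p against the input, capped at 400 according to the values. The same deposited lists give a log2 fold of IP over input for each peak, as the values show. A further deposited list of reproducible peaks has both measures, and how the authors combined the replicates in it is not known.

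Counts came from 36817 gene identifiers, of which 434 were tRNA names. Of 29754 Ensembl identifiers, 28576 matched the symbol table after the version was dropped. Depth was 4643494, 1244213 and 7807540 counted reads in IP replicate 1, IP replicate 2 and the input, of which 67.6%, 62.6% and 30.7% were exonic. The 10 identifiers with most reads took 5.60%, 5.24% and 6.35% of the gene reads. Shares of reads have exact Clopper-Pearson intervals at 95%.

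Exonic reads (coding sequence, UTR and non-coding exon) were summed per gene, and genes with at least 10 reads in at least 2 of the 3 libraries were tested with edgeR's quasi-likelihood test (glmQLFit, glmQLFTest) after TMM normalisation. Counts per gene and region went through the same test in 1 fit, with TMM normalisation over exonic and intronic rows together. A gene or region was called at a Benjamini-Hochberg adjusted p under 0.05. The spread came from the 2 IP libraries alone, with 1 residual degree of freedom, and the lone input was assumed to vary like them. In the gene fit the common dispersion was 0.0272, a coefficient of variation of 16.5%, and the prior degrees of freedom were 75.9. In the region fit they were 0.0356, 18.9% and infinite, so the quasi-likelihood spread was not estimated region by region. CPM values are relative to TMM-scaled exonic reads, and log2 folds per replicate used a prior count of 2. A feature with 0 input reads was given a fold against a floor of 3 reads, and one with 1 to 3 input reads an IP to input ratio with its 95% counting interval. In simulated data 200 genes were changed by known folds, and 10117 genes were tested. The test recovered 28.3% of genes changed 2-fold and 93.1% of those changed 4-fold, and 4 calls (3.60%) were false. All simulated libraries, the input included, had the spread estimated from the 2 IP libraries. The false share therefore does not give the error rate of the real calls.

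Median log2 folds of 19 gene lists were compared with 10000 random lists of the same size matched on deciles of input reads, two-sided, with Benjamini-Hochberg adjustment. The smallest p this can give is 0.0002. The lists were P-body and mRNA decay factors, cytosolic ribosomal proteins, translation factors and other 5' TOP mRNAs, chromatin modifiers, chromatin architecture factors, tumour suppressors, leukaemia-promoting regulators, myeloid differentiation genes, other blood lineage markers, interferon-stimulated genes, autophagy genes, proteasome subunits, glycolysis enzymes, mitotic and cell cycle genes, nuclear-retained non-coding RNAs, ZNF genes, nuclear-encoded respiratory chain subunits, mitochondrially encoded mRNAs and replication-dependent histone genes. The groups, the tests, the alternatives, these lists and the rule for named genes were chosen before the data were examined. Another 3 lists, of immediate early and inflammatory response genes, the same without members already seen, and selenoproteins, were chosen after seeing the data.

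The rule named DDX6, the 10 called genes with the largest and the 10 with the smallest log2 fold among those with one direction in both IP libraries and a mean log2 read level above the median, and up to 3 members per list with the smallest p. For regions it named the 5 genes with the largest fold in the 3'UTR, coding sequence, 5'UTR and intron, and for the reproducible list the 10 peaks with the largest fold and the 5 genes with most peaks. Members of small counts were named in addition, after their values were seen. A few genes that the rule or a list takes in are not reported here.

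Peaks were called significant at a -log10 p of at least 3 and a log2 fold of at least 3, the usual eCLIP thresholds, and compared with bedtools at an overlap of at least 1 base on the same strand. Overlap and list membership were tested with two-sided Fisher's exact tests, the latter among the 10392 tested genes. Of the 497 gene identifiers in the reproducible list, 417 were among these. Agreement between the replicates was set beside 100 simulated sets of unchanged IP libraries against the same input. Groups of this size allow no count over other splits of the samples.

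The alternatives were DESeq2's Wald test, scaling to library size alone, median-of-ratios size factors, no filter beyond 1 read, a filter of 30 reads, intronic reads included, coding and 3'UTR reads only, each IP replicate left out, region shares without the 1% of genes with most input reads or without mitochondrially encoded genes, no matching of random lists, other backgrounds for the Fisher tests, stricter and looser peak thresholds, other overlap rules, the upper 50% of the reproducible list and prior counts of 0.5 and 5. Random lists of protein-coding genes, thinning of IP replicate 1 and the input to the depth of IP replicate 2, and merging of touching peaks were added after seeing the data. Sequence motifs and GC content were left out because no genome was used here.

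The software was Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, bedtools 2.31.1, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.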

Results

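RNA bound by the helicase DDX6 was measured by eCLIP in MOLM-13 cells, a human acute myeloid leukaemia line. DDX6 represses translation, promotes mRNA decapping and is needed for P-bodies, the cytoplasmic granules that hold untranslated mRNA. In eCLIP, RNA is cross-linked to protein by ultraviolet light, trimmed with RNase, recovered with an antibody and sequenced beside an input library made without the antibody. There were 2 DDX6 immunoprecipitation (IP) libraries and 1 input library. The tables held 4643494 counted reads for IP replicate 1, 1244213 for IP replicate 2 and 7807540 for the input. The series title links storage of RNA in P-bodies to chromatin organisation in myeloid leukaemia, so the comparisons below ask which transcripts and which parts of them were recovered with DDX6. Nothing says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Intervals and read floors cover counting error only.

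Reads of the DDX6 IP lay in coding sequence more often than those of the input. Coding sequence held 33.4% ± 1.84 (SD, n = 2) of the IP reads and 10.03% of the input reads, a ratio of 3.33. The 3'UTR held 20.5% ± 2.86 (SD, n = 2) of the IP reads and 10.3% of the input reads, a ratio of 1.99, and the 5'UTR 3.64% ± 0.338 (SD, n = 2) and 1.43%, a ratio of 2.55. Introns showed the reverse, with 23.5% ± 1.97 (SD, n = 2) of the IP reads and 60.8% of the input reads, so the input share was 2.59 times the IP share. For these 4 regions the distance from the input was larger than the gap between the replicates. The replicates had 34.7% and 32.1% in coding sequence and 22.1% and 24.9% in introns. All shares are of all counted reads, so the lower intron share in the IP raises the other shares as a group. Exonic reads as a whole took 67.6% and 62.6% of IP replicate 1 and IP replicate 2 and 30.7% of the input. The 3'UTR ratio therefore does not show that 3'UTR reads rose among exonic reads.

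tRNA reads took 2.56% of IP replicate 1, 5.18% of IP replicate 2 and 1.19% of the input. Intergenic reads took 4.05%, 3.78% and 2.63%. Introns of non-coding genes made up 3.62% ± 0.0695 (SD, n = 2) of the IP reads and 4.72% of the input reads, and exons of non-coding genes 7.58% ± 0.810 (SD, n = 2) and 8.94%. For the exons of non-coding genes the direction rested on a few abundant RNAs, because the ratio of 0.848 became 1.52 without the 1% of genes with most input reads. No share has a replicate check on the input side. Exact Clopper-Pearson intervals (95%) were narrow, for example 32.0% to 32.1% for coding sequence in IP replicate 2.

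**Figure D1:**
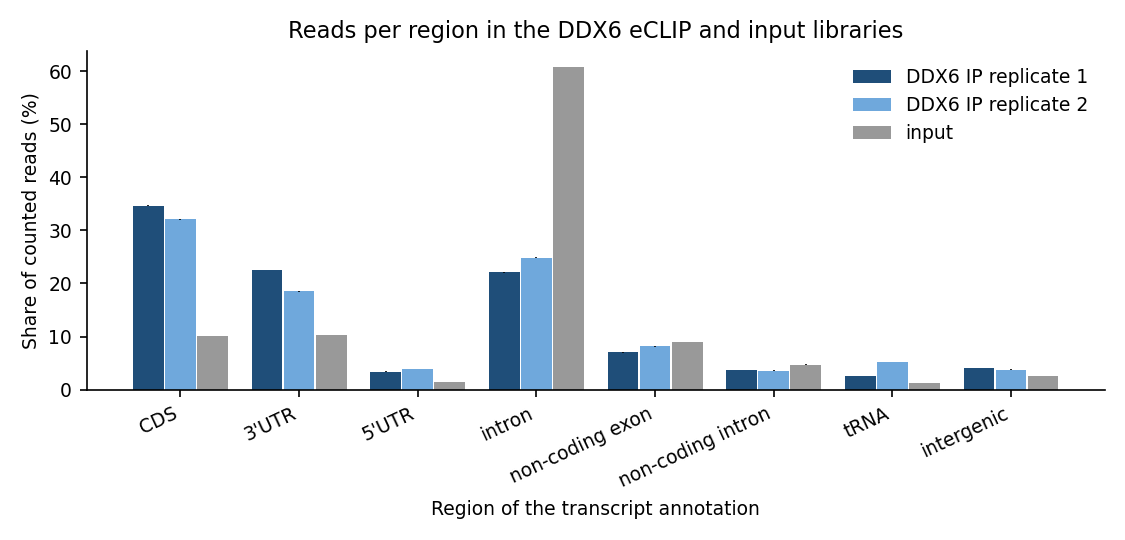
Share of counted reads (%, vertical axis) in each region of the annotation (horizontal axis) for both DDX6 IP libraries and the input. Coding sequence reached 34.7% and 32.1% in the IP libraries against 10.03% in the input, and introns 22.1% and 24.9% against 60.8%.

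Tested gene by gene, coding regions were higher in the DDX6 IP for 4183 of 8169 genes and lower for 17. The 5'UTR was higher for 672 of 2025 genes and lower for 91, and the 3'UTR was higher for 1717 of 7194 and lower for 491. Introns were lower for 7601 of 9153 genes and higher for 235, with a median log2 fold of -1.93, and introns of non-coding genes were lower for 769 of 1299 and higher for 66. Non-coding exons were higher for 181 and lower for 214 of 985. The median log2 fold was 1.02 for coding regions, 0.74 for 5'UTRs and 0.28 for 3'UTRs. Within the same gene, the coding region exceeded the 3'UTR by a median of 0.83 log2, and did so in 86.8% of 6552 genes. These calls come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05 over 28825 gene regions, of which 7054 were higher and 9183 lower. With scaling to library size alone 11607 were higher and 6947 lower, and DESeq2 gave 3390 and 5907. The read filter can be passed by the IP libraries without input reads, but not by the input alone. With no filter beyond 1 read 5048 were higher and 10857 lower, and at 30 reads or more 5721 and 6346. The main scaling took exonic and intronic rows together, so the counts and medians of each region are relative to that mixture. Differences between regions of the same gene do not depend on scaling.

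**Figure D2:**
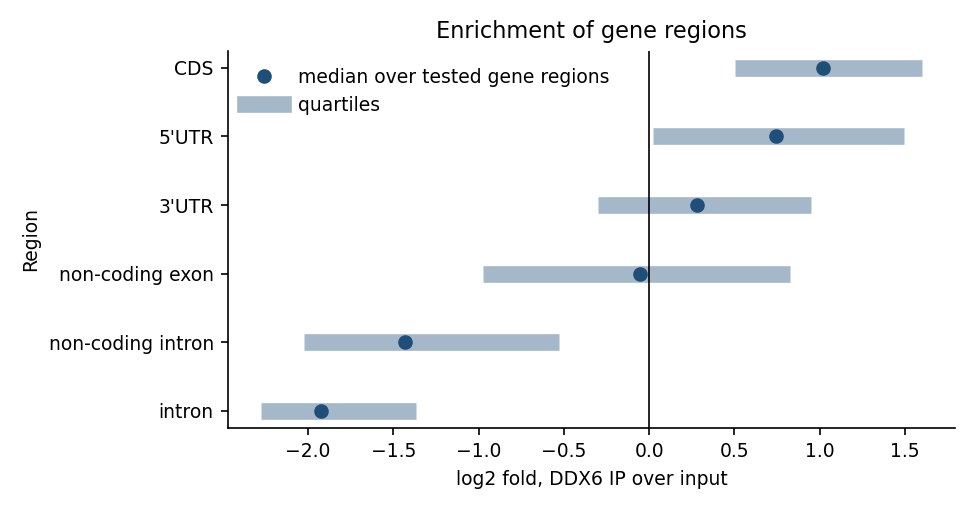
Median (point) and quartiles (bar) of the log2 fold of DDX6 IP over input (horizontal axis) over the tested genes of each region (vertical axis). The medians ran from 1.02 for coding regions to -1.93 for introns, relative to the scaling used in the test.

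TNF, which encodes a central inflammatory cytokine, was among the 5 highest genes in each exonic region. Its 3'UTR was 19.1-fold higher in the IP (6524, 1265 and 318 reads in IP replicate 1, IP replicate 2 and input), its coding region 30.2-fold and its 5'UTR 43.5-fold. The other leading 3'UTRs were those of SPRY2 (15.04-fold), GEMIN5 (12.8-fold), ADRB1 (12.4-fold) and ZFP36 (12.1-fold), which encodes a protein that destabilises mRNAs with AU-rich elements. The leading 5'UTRs were those of RPL37A (63.5-fold), the early response gene IER3 (61.0-fold) and the chemokine gene CXCL8 (48.7-fold). The lead of RPL37A rested on IP replicate 2 (6.43 log2), since its 4.87 log2 in IP replicate 1 lay under TNF (5.56), CXCL8 (5.40) and IER3 (5.40). The 5'UTR of the histone gene H2BC12 had 3 input reads and a ratio of 34.4 with a 95% counting interval of 11.5 to 169, or 3.79 log2 in IP replicate 1 and 5.18 in IP replicate 2. Among coding regions, that of ZNF57 was 29.6-fold higher. Folds of regions are scaled over exons and introns together, and the gene folds further below over exons alone. Both sets are therefore on unlike scales, and the fold of a region can exceed that of its whole gene.

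Some of the highest folds came from single short sites. The coding region of AJAP1 had 87 and 76 IP reads and 0 input reads, at least 30.9-fold higher in IP replicate 1 and at least 104-fold in IP replicate 2 against a floor of 3 input reads. Its significant peaks in IP replicate 1 formed 1 site of 27 bases (hg19, chromosome 1, 4772075 to 4772101). GRIK4, with 2 input reads, had a coding-region ratio of 68.5 (95% counting interval 18.7 to 571), with 3.29 log2 in IP replicate 1 and 6.72 in IP replicate 2, and 1 site of 20 bases in IP replicate 1 (hg19, chromosome 11, 120732809 to 120732828). The intron of AL590867.1 had 0 input reads and was at least 32.7-fold higher in IP replicate 1 and at least 108-fold in IP replicate 2, with 1 site of 21 bases in both IP lists (hg19, chromosome 6, 153584505 to 153584525). Other leading introns were those of NALF1, with 3 input reads and a ratio of 43.1 (95% counting interval 14.5 to 212), PCDH15 (11.8-fold, with 2.559 and 4.004 log2 in IP replicate 1 and IP replicate 2) and NRG1 (10.2-fold, with 2.72 and 3.75).

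Summed over exons, 1739 of 10392 genes (16.7%) were higher in the DDX6 IP and 1188 (11.4%) lower, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The difference was at least 2-fold for 1247 of the higher and 831 of the lower genes. Of the 2927 called genes, 2925 had the same direction in both IP libraries. The exceptions, TWF1 (1.59 and -0.17 log2) and RNA5SP74 (-1.96 and 0.02 log2), were named after their values were seen. Protein-coding genes were higher 1660 times and lower 886 times among 9455. Non-coding genes were higher 79 times and lower 302 times among 937, with a median log2 fold of -0.65. These counts depend on the scaling, on the reads counted, on the read filter and on the spread that edgeR estimated with 1 residual degree of freedom. Scaling to library size alone moves the median gene by 1.24 log2 and gave 6990 higher and 141 lower, DESeq2 gave 679 and 256, and libraries thinned to the depth of IP replicate 2, an alternative chosen after seeing the data, gave medians of 322 and 228 over 21 draws, of which 6 gave none. With intronic reads included 2531 genes were higher and 2394 lower, but these took in just 1040 of the 1739 higher and 488 of the 1188 lower genes. At 30 reads or more 1100 were higher and 857 lower.

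The DDX6 transcript itself (ENSG00000110367.7) had 510 ± 86.1 (SD, n = 2) CPM of exonic reads in the IP and 336 in the input. Its log2 fold of 0.61 (SE 0.28) did not pass the test (edgeR adjusted p = 0.0946). It passed with library-size scaling (1.84 log2, edgeR adjusted p = 3.46e-06) and with intronic reads included (1.13 log2, edgeR adjusted p = 5.31e-05), and the adjusted p ran from 3.46e-06 to 0.384 over its 7 tested alternatives.

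TNF (ENSG00000232810.3) reached 4076 ± 498 (SD, n = 2) CPM of exonic reads in the IP and 248 in the input, a 16.4-fold difference (log2 fold 4.04, SE 0.45, edgeR adjusted p = 3.51e-11). Of the 10 leading genes, 7 were tRNAs encoded in mitochondrial DNA, which serve mitochondrial translation. MT-TF was highest of these at 6.09 log2 (SE 0.45, edgeR adjusted p = 1.02e-18, 3664, 1160 and 42 reads), followed by MT-TM (4.82), MT-TI (4.79), MT-TT (4.76), MT-TG (4.76), MT-TL2 (4.50) and MT-TP (4.02). The remaining leading genes were GRIK4, with 2 input reads and a ratio of 45.4 (95% counting interval 12.4 to 378), and a Y RNA (ENSG00000199580.1, 4.03 log2). IP replicate 2 lay above IP replicate 1 by over 1 log2 for GRIK4 (6.36 and 2.94), the Y RNA (4.69 and 2.56), MT-TI (5.30 and 3.93), MT-TG (5.23 and 3.91), MT-TL2 (4.81 and 3.57) and MT-TT (5.20 and 4.06). With DESeq2 the adjusted p was 0.0533 for GRIK4 and 0.0632 for the Y RNA, while the lowest among their alternatives were 1.65e-28 and 7.87e-32.

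The lowest genes were mostly small nuclear or nucleolar RNAs and the hosts of small RNAs. ENSG00000252310.1, which has no symbol in the name table, was 31.5-fold lower in the IP (302, 183 and 10971 reads, log2 fold -4.98, SE 0.37, edgeR adjusted p = 1.63e-18). SNHG25 was at -4.58 log2, SNHG12 at -3.52 and SNHG8 at -3.28, and these are host genes of small nucleolar RNAs. The small nucleolar RNA SNORA31B was at -4.21 log2, the microRNA host MIR17HG at -3.42 and the spliceosomal RNA RNU4-2 at -3.32, which DESeq2 did not call (adjusted p = 0.134, against 6.81e-21 as the lowest of its alternatives). ENSG00000259001.2 (-3.93), RNA5SP225 (-3.72) and HNRNPU-AS1 (-3.39) completed the 10. IP replicate 1 lay below IP replicate 2 by over 1 log2 for RNU4-2 (-4.56 and -2.60), SNHG25 (-5.21 and -3.92), MIR17HG (-3.82 and -2.54) and ENSG00000252310.1 (-5.70 and -4.42).

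Fold values of the replicates were close across genes. The log2 folds of IP replicate 1 and IP replicate 2 over the input had a Pearson correlation of 0.840 and a Spearman correlation of 0.830 across 10392 genes, which are not independent replicates. Unchanged IP libraries simulated with a shared, also simulated input gave a mean Pearson correlation of 0.423 and at most 0.448 in 100 sets. The covariance was 0.755 against a simulated 0.102, a difference of 0.654, and 82.5% of genes had the same sign in both replicates against a simulated 64.8%. With 1 input library its own spread could not be estimated. The simulated input varied as the IP libraries do, so part of the excess may come from further deviation of the real shared input.

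**Figure D3:**
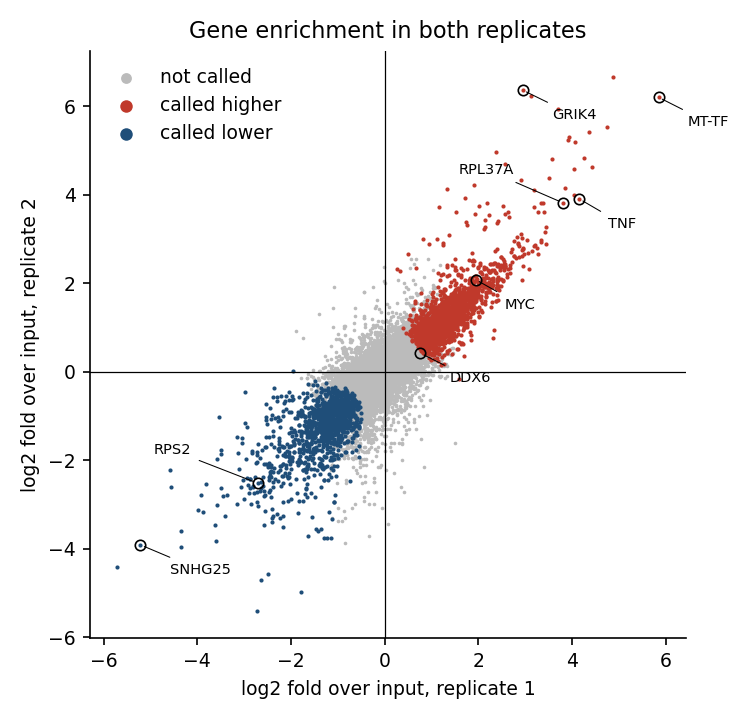
Log2 fold of exonic reads over the input in IP replicate 1 (horizontal axis) and IP replicate 2 (vertical axis) for 10392 genes, with the 1739 genes called higher in red and the 1188 called lower in blue. MT-TF, TNF and RPL37A lay high and SNHG25 low in both replicates, and the cloud had a Pearson correlation of 0.840.

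Of 19 gene lists, 10 differed from random lists matched on input reads, 7 higher and 3 lower in the IP. Each list's p came from 10000 random lists (two-sided permutation) with Benjamini-Hochberg adjustment, and describes these libraries, since genes are not replicates. With scaling to library size alone, the median of every one of the 19 lists except the nuclear-retained non-coding RNAs was above 0, so higher and lower are relative to the typical gene.

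C2H2 zinc finger genes named ZNF, mostly DNA-binding repressors, stood highest. Of 319 tested, 178 were higher and 13 lower, or 193 and 14 adjusted over the list alone, with a median log2 fold of 1.16, which is 1.11 above matched lists (permutation adjusted p = 0.00127). ZNF92 (3.07 log2), ZNF267 (3.07) and ZNF507 (2.90) had the smallest p. Chromatin modifiers had 43 higher and 1 lower of 91, or 50 and 1 adjusted over the list alone, with a median of 0.73 (permutation adjusted p = 0.00127). They included the histone demethylase gene KDM5B (2.08), the remodeller gene CHD7 (2.11) and the histone methyltransferase gene SETDB1 (1.78). EZH1 was the lower one (-0.96), named after its value was seen. Chromatin architecture factors had 10 higher and 3 lower of 36, or 12 and 3 adjusted over the list alone, with a median of 0.40 (permutation adjusted p = 0.0106). The cohesin gene SMC3 was higher (1.28), and the high-mobility-group genes HMGN1 (-1.43), HMGA1 (-1.33) and, named after its value was seen, HMGB1 (-1.08) were lower, although with library-size scaling neither HMGN1 (-0.19) nor HMGA1 (-0.09) passed. The architecture call ended without matching on input reads (permutation adjusted p = 0.057, range over 10 alternatives 0.00887 to 0.057).

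Histone genes had 18 higher and 0 lower of 56, or 21 and 0 adjusted over the list alone, with a median of 0.49 (permutation adjusted p = 0.0019). Examples were HIST1H2BM (1.39), HIST1H3A (1.33) and HIST1H4K (1.52, which DESeq2 did not call, adjusted p = 0.103). The symbol pattern of this list also took in H1-10, which is not replication-dependent and was not called. No source used here says how the counting treated reads that match several near-identical histone or zinc finger genes, so the values of single members are uncertain. The same holds for tRNAs, Y RNAs, mitochondrial genes, ribosomal protein genes with pseudogenes, overlapping genes and antisense genes, since the treatment of strand is not given either.

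Tumour suppressor genes had 20 higher and 0 lower of 46, or 21 and 1 adjusted over the list alone, with a median of 0.50 (permutation adjusted p = 0.00228). TNFAIP3, which restrains NF-kappa-B signalling, was at 2.20, the Hippo kinase gene LATS2 at 1.71 (not called with intronic reads included, 0.47) and the cytokine signalling inhibitor gene SOCS1 at 2.25. Leukaemia-promoting regulators had 13 higher and 3 lower of 31, both over all genes and adjusted over the list alone, with a median of 0.51 (permutation adjusted p = 0.0038). The histone demethylase family gene JMJD1C (2.11, not called with intronic reads included, 0.52), MYC (2.01) and the RNA methylation reader gene YTHDF2 (1.33) were higher, and NRAS (-0.96), MSI2 (-0.86) and IGF2BP2 (-0.71), named after their values were seen, were lower. With intronic reads included this list no longer stood apart (excess 0.09, permutation adjusted p = 0.658, range over 10 alternatives 0.00127 to 0.658). Mitotic and cell cycle genes had 14 higher and 1 lower of 45, or 17 and 1 adjusted over the list alone, with a median of 0.35 (permutation adjusted p = 0.0289). They included CDT1 (1.55), TTK (1.40) and CDC6 (1.41), while CDC25B, named after its value was seen, was lower (-0.84). That call ended without matching (permutation adjusted p = 0.0638, range over 10 alternatives 0.000633 to 0.0638) and with coding and 3'UTR reads only (0.0592).

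Genes for P-body and mRNA decay factors, the partners of DDX6, were not called as a list. Of 49, 11 were higher and 5 lower, both over all genes and adjusted over the list alone, with a median of 0.27 (permutation adjusted p = 0.0536). ZFP36 (2.88), the decapping factor gene DCP1B (2.19) and the exonuclease gene XRN1 (1.504) were higher. LSM5 (-1.39), LSM4 (-1.22), PABPC4 (-0.81), LSM3 (-0.76) and AGO3 (-0.67), named after their values were seen, were lower. DCP1B was not called with intronic reads included (0.07 log2, edgeR adjusted p = 0.890).

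Cytosolic ribosomal protein mRNAs were lower in the IP for 30 of 76 and higher for 1, or 32 and 1 adjusted over the list alone, with a median of -0.48 that became 0.75 with library-size scaling. The list lay 0.31 log2 under matched lists (excess -0.31, permutation adjusted p = 0.0106), and 0.88 above them when intronic reads were included (permutation adjusted p = 0.000633, range over 10 alternatives 0.000633 to 0.0232). RPS2 (-2.62) and RPL17 (-1.93) had the smallest p among the lower members. The higher member was RPL37A (ENSG00000197756.5), which was 14.01-fold higher with 35623, 8910 and 1765 reads (log2 fold 3.81, SE 0.50, edgeR adjusted p = 5.15e-09). Nuclear-encoded respiratory chain subunits had 0 higher and 9 lower of 75, or 0 and 6 adjusted over the list alone, with a median of -0.40 (permutation adjusted p = 0.0038) that became 0.84 with library-size scaling. ATP5F1E (-1.42), SDHD (-1.33) and UQCRFS1 (-1.21) were the examples with the smallest p, of which UQCRFS1 turned to 0.03 with library-size scaling. Without IP replicate 1 this call was lost at a permutation adjusted p of 0.0505, and with intronic reads it turned to an excess of 0.23 (0.0707, range over 10 alternatives 0.0012 to 0.0707).

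Nuclear-retained non-coding RNAs had 11 lower and 1 higher of 15, both over all genes and adjusted over the list alone. Their median was -2.08 (permutation adjusted p = 0.00127), and stayed below 0 with library-size scaling (-0.84). Non-coding genes as a whole had a median of -0.65, and the random lists were matched on input reads and not on coding status. The location of the list's RNAs in the cell was not measured, so its median does not show an effect of nuclear retention. The members with the smallest p, SNHG12, SNHG5 (-2.77) and SNHG8, are host genes of small nucleolar RNAs. NEAT1 (-2.14), which scaffolds nuclear paraspeckles, was also lower, and NORAD (1.54), a largely cytoplasmic RNA that binds PUMILIO proteins, was the higher one. Both were named after their values were seen. The call ended with intronic reads included (permutation adjusted p = 0.0589, range over 8 alternatives 0.00072 to 0.0589).

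The other 8 lists were not called. Translation factors and other 5' TOP mRNAs had 0 higher and 5 lower of 24, both over all genes and adjusted over the list alone (median -0.38, or 0.86 with library-size scaling, permutation adjusted p = 0.363). With intronic reads included this list was called higher (excess 0.69, permutation adjusted p = 0.00163, range over 10 alternatives 0.00163 to 0.513). The lower members were EIF5A (-1.499), TPT1 (-1.15), EEF1D (-1.09) and, named after their values were seen, HNRNPA1 (-0.81) and EEF1G (-0.69). With library-size scaling TPT1 (0.09) and EEF1D (0.14) turned. Myeloid differentiation genes went both ways, with 6 higher and 9 lower of 29, also adjusted over the list alone (permutation adjusted p = 0.268). The transcription factor genes EGR1 (1.93), EGR2 (2.16) and CEBPB (1.73) were higher. The granule protein genes LYZ (-1.44), MPO (-1.29) and ELANE (-1.18), named after their values were seen, were lower. At 30 reads or more the list was called lower (excess -0.46, permutation adjusted p = 0.0274, range over 10 alternatives 0.0274 to 0.953), and its median of -0.25 became 0.98 with library-size scaling. Of the markers of other blood lineages 3 had enough reads, with 0 higher and 1 lower, also adjusted over the list alone (permutation adjusted p = 0.271). CD4, which monocytic cells also carry, was lower (-1.44), and CD3D (-0.61) and NKG7 (-0.23) did not pass. With library-size scaling CD3D turned to 0.63, which did not pass, and NKG7 to 1.01, which did.

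Interferon-stimulated genes had 2 higher and 0 lower of 20, or 1 and 0 adjusted over the list alone (permutation adjusted p = 0.613), namely DTX3L (0.94) and IFIT2 (1.04). DESeq2 called neither of these (adjusted p = 0.149 and 0.389). Autophagy genes had 3 higher and 5 lower of 38, both over all genes and adjusted over the list alone (permutation adjusted p = 0.795). GABARAP (-1.28), LAMP2 (-0.87, or 0.36 with library-size scaling) and SQSTM1 (-0.86, or 0.37) were lower. So were ATG4B (-1.03) and LAMP1 (-0.87), while ATG4C (1.36), PIK3R4 (0.95) and CALCOCO2 (0.80) were higher, these 5 being named after their values were seen. Proteasome subunits had 0 higher and 2 lower of 30, or 0 and 1 adjusted over the list alone (permutation adjusted p = 0.613). These were PSMD11 (-1.04) and PSMB2 (-0.78), which library-size scaling turned to 0.20 and 0.46. Glycolysis genes had 3 higher and 2 lower of 18, both over all genes and adjusted over the list alone (permutation adjusted p = 0.795). SLC2A1 (1.48), HK2 (1.22) and SLC2A3 (0.81) were higher and PGK1 (-1.05, or 0.18 with library-size scaling) and TPI1 (-0.71) lower, with SLC2A3 and TPI1 named after their values were seen. The glycolysis list was called higher with intronic reads included (excess 0.72, permutation adjusted p = 0.00903, range over 10 alternatives 0.00903 to 0.953). Mitochondrially encoded mRNAs had 2 higher and 3 lower of 13, both over all genes and adjusted over the list alone (permutation adjusted p = 0.613). MT-ND3 (1.47) and MT-ND2 (1.23) were higher, and MT-ATP8 (-1.90), MT-ND4 (-1.14, or 0.09 with library-size scaling) and MT-ATP6 (-0.93) lower, with MT-ND2 and MT-ATP6 named after their values were seen. With intronic reads included the mitochondrial mRNAs were called higher (excess 1.29, permutation adjusted p = 0.000633, range over 10 alternatives 0.000633 to 0.795) and MT-ND4 turned to 0.04.

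The calls of several list members named above ended under an alternative. With intronic reads included, edgeR no longer called HMGN1, HMGA1, EIF5A, TPT1, CD4, GABARAP, LAMP2, SQSTM1, PSMB2, PGK1, ATP5F1E or UQCRFS1. DESeq2 did not call GABARAP, LAMP2, SQSTM1, PSMD11, PSMB2, SDHD or UQCRFS1, with log2 folds from -1.34 for SDHD to -0.76 for PSMB2. Library-size scaling ended the calls of HMGN1, HMGA1, EIF5A, CD4, GABARAP, ATP5F1E and SDHD besides those that it turned. PSMB2 and IFIT2 were not called without the read filter or at 30 reads or more, TPT1 without the read filter, and EEF1D and IFIT2 with coding and 3'UTR reads only.

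**Figure D4:**
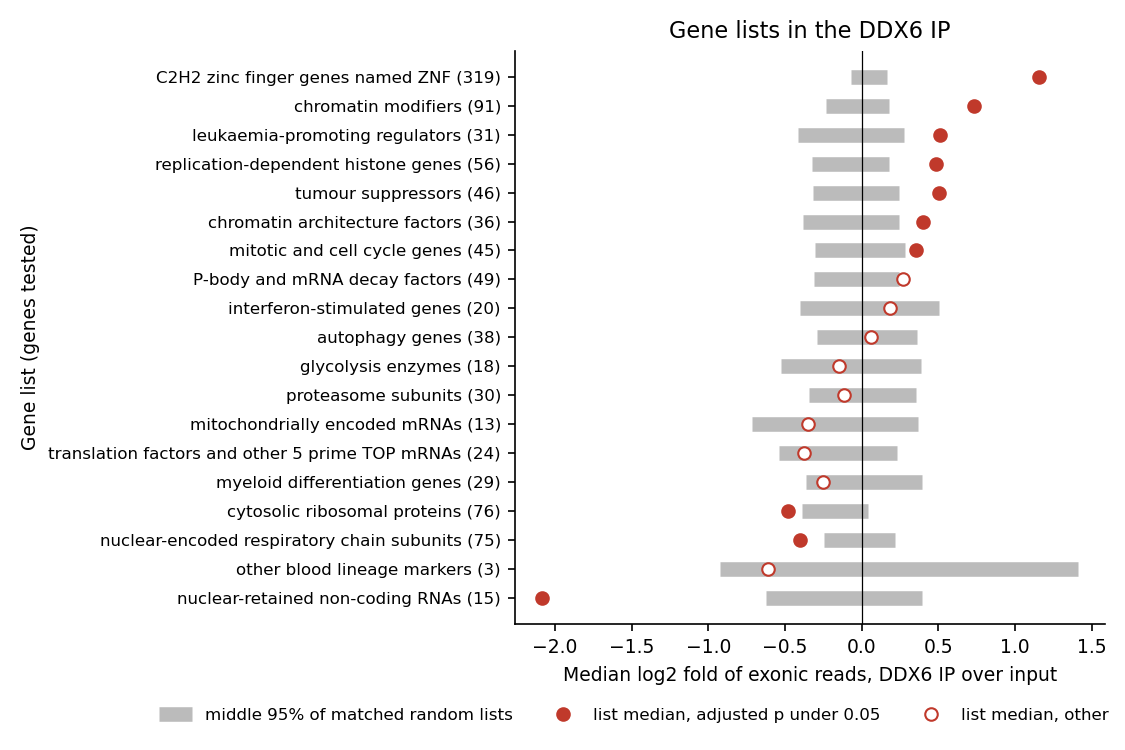
Median log2 fold of exonic reads in the DDX6 IP over the input (horizontal axis) for 19 gene lists (vertical axis, genes tested in brackets), with the middle 95% of 10000 matched random lists as bars and lists with an adjusted p under 0.05 as filled points. ZNF genes stood at 1.16, ribosomal protein genes at -0.48 and nuclear-retained non-coding RNAs at -2.08, and with library-size scaling every median except that of the nuclear-retained RNAs (-0.84) was above 0.

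The authors' peak lists placed most significant DDX6 sites in coding sequence. IP replicate 1 had 123298 peaks, of which 14133 (11.5%) reached a log2 fold of 3 over input and a -log10 p of 3, and IP replicate 2 had 62411, of which 8036 (12.9%) did. Coding sequence held 71.1% of the significant peaks of IP replicate 1 and 67.0% of those of IP replicate 2, the 3'UTR 18.9% and 17.5%, and introns 1.37% and 3.55%. Of all called peaks, coding sequence already held 54.6% and 58.1%, the 3'UTR 20.5% and 20.8%, and introns 15.5% and 11.6%. Significant peaks fell in 3838 and 3337 genes. Of the peaks with a log2 fold of at least 3, 73.7% passed the p threshold in IP replicate 1 and 44.0% in IP replicate 2, which had fewer reads. Fold and p of each peak are the authors' own values.

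Of the significant peaks, 3129 of IP replicate 1 (22.1%) overlapped a significant peak of IP replicate 2 by at least 1 base on the same strand, and 2703 of IP replicate 2 (33.6%) did the reverse. Among the 34950 peaks of IP replicate 1 that overlapped any peak of IP replicate 2, 3129 were significant in both lists. Independent lists would share 1004, or 3.12 times fewer (two-sided Fisher's exact test, odds ratio 10.5, with a p too small for the software to represent). The log2 folds of these overlapping peaks had a Pearson correlation of 0.724. Both lists were normalised to the same input, so independent lists are not what unchanged IP libraries would give. What a shared input produces was simulated for genes, with an input that varied like the IP libraries, and not for peaks. Neither the excess nor the correlation therefore measures binding that both replicates share.

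ZEB2, TNF, CPEB2, ZFP36L2 and RPL37A held the most peaks of the authors' reproducible list. ZEB2, a zinc finger transcription factor gene, had 34 peaks, 26 of them in coding sequence, 5 in the 3'UTR and 3 in the 5'UTR (hg19, chromosome 2, between 145145978 and 145277628). TNF had 26, with 17 in coding sequence, 8 in the 3'UTR and 1 in the 5'UTR (chromosome 6, between 31543463 and 31546059). CPEB2, which encodes a translational regulator, had 25, with 16 in coding sequence and 9 in the 3'UTR (chromosome 4, between 15009096 and 15071072). ZFP36L2, which encodes a relative of ZFP36, had 25, with 21 in the 3'UTR and 4 in coding sequence (chromosome 2, between 43449549 and 43453443). RPL37A had 25, all annotated as coding sequence (chromosome 2, between 217363565 and 217366131).

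The reproducible list held 1587 peaks in 475 genes, or 1105 sites once touching peaks were merged, an alternative chosen after seeing the data. Coding sequence held 935 (58.9%), the 3'UTR 339 (21.4%), the 5'UTR 125, non-coding exons 89, tRNAs 38, introns 37, introns of non-coding genes 20 and microRNAs 4. The median log2 fold was 3.84 (14.4-fold) and the median width 48 bases. Of the peaks, 1333 (84.0%) overlapped a significant peak of both replicates' lists.

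The 10 peaks with the largest fold in that list lay at 5 sites, outside coding sequence and UTRs. They were in introns of KCNQ3 (hg19, chromosome 8, 133208156 to 133208183, log2 fold 9.95), OPA1 (chromosome 3, 193330826 to 193330855, 9.42) and SYCP2L (chromosome 6, 10887835 to 10887860, 8.82), in an intron of the non-coding gene LINC01643 (chromosome 22, 34558591 to 34558619, 8.82) and at a tRNA gene with anticodon TTA annotated as a suppressor (chromosome 17, 58863622 to 58863639, 8.76). Exonic reads of the host were few for KCNQ3 (10, 5 and 10 reads in IP replicate 1, IP replicate 2 and input) and more for OPA1 (494, 100 and 465). Suppressor tRNA genes with anticodon TTA had 225, 199 and 0 reads in all, so that fold may have no input reads under it. Input reads under the other sites were not counted here. The size of all these folds is therefore uncertain, as it may rest on how the authors treated few or 0 input reads.

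Genes of 6 of the 19 lists carried reproducible peaks more often than the other tested genes, of which about 4.0% did (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the lists). Chromatin modifiers had them in 15 of 91 genes (16.5%, odds ratio 4.86, Fisher's exact adjusted p = 5.57e-05) and ZNF genes in 25 of 319 (7.84%, odds ratio 2.10, Fisher's exact adjusted p = 0.00593). Both also passed against genes matched on input reads. Tumour suppressors had them in 9 of 46 (19.6%, Fisher's exact adjusted p = 0.000691), leukaemia-promoting regulators in 7 of 31 (22.6%, 0.00115), mitotic genes in 6 of 45 (13.3%, 0.0331) and P-body factors in 6 of 49 (12.2%, 0.0414). Against genes matched on input reads these 4 did not pass (permutation adjusted p = 0.0912, 0.196, 0.415 and 0.588), though they passed against all genes with input reads, the other alternative (adjusted p = 5.9e-06, 1.67e-05, 0.00149 and 0.00198). Ribosomal protein genes had 1 of 76, and passed as fewer only against matched genes (permutation adjusted p = 0.0038). The 12 remaining lists did not pass, among them the chromatin architecture factors with 4 of 36 (Fisher's exact adjusted p = 0.149), which passed against all genes with input reads (0.0199) but not against matched genes.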

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

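The tests on tRNA reads in this part were chosen after the tRNA shares had been seen. Reads outside the gene-level tests appeared in the IP libraries above their level in the input. tRNA reads took 2.565% of IP replicate 1 and 5.176% of IP replicate 2 against 1.191% of the input. Intergenic reads took 4.047% and 3.778% against 2.626%. Their ratios of 1.54 and 1.44 lay under those of coding sequence, 5'UTR and 3'UTR. All these are shares of all counted reads, which the fall of intronic reads in the IP raises. The intergenic rise therefore does not show that such reads were recovered with DDX6.

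Of 46 isoacceptors (tRNA genes summed by amino acid and anticodon) with at least 100 input reads, 31 had a larger share than the input in both IP libraries, by 4.57 and 5.02 log2 for Lys-TTT in IP replicate 1 and IP replicate 2, and 5 a smaller one, with Ser-ACT at -3.33 and -3.01. These ratios are scaled to all counted reads, a scale on which the median tested gene rose by 1.24 log2. The median isoacceptor was at 1.07 log2 in IP replicate 1, under that gene, and at 2.28 in IP replicate 2. The level differed between the replicates, since 45 of 46 isoacceptors were higher in IP replicate 2, by a median of 1.12 log2. An equal carry-over of all tRNAs could raise their share, but it predicts a spread between isoacceptors of under 0.5, and the standard deviation was 1.638 in the replicate with the smaller value, which argues against it as the whole cause. Carry-over that differs between tRNAs stays open, and the design gives no biological group to test.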

How the results depend on the processing

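The thinned libraries, the coding-only random lists and the merged peaks were chosen after seeing the data. No paired analysis was possible because the input has 1 library, so the IP replicate numbers have no partner. Leaving out 1 IP leaves no residual degrees of freedom, so it gives fold values and no count of calls. Of the 1739 higher genes, 1739 kept their direction without IP replicate 2 and 1738 without IP replicate 1, and the 1188 lower genes kept theirs in both. Of the higher regions 7050 and 7035 of 7054 did so, and of the lower ones 9183 and 9179 of 9183. These genes and regions were called from both replicates together, so their direction in either replicate alone was nearly fixed beforehand. The counts are therefore no independent check. Except where a sentence names it, the cause was not tested. With IP replicate 1 and the input thinned to the depth of IP replicate 2, the median of 21 draws was 322 higher and 228 lower genes, with ranges of 0 to 1147 and 0 to 1012. In 6 of the draws edgeR called no gene, although 2135 to 3046 genes per draw had an unadjusted p under 0.05, and the prior degrees of freedom ran from 1.39 to infinite between draws, so the number of calls rests on an estimate that 1 residual degree of freedom does not fix.

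DESeq2 gave 679 higher and 256 lower genes, and 3390 higher and 5907 lower regions. Library-size scaling gave 6990 and 141 genes and 11607 higher regions, and turned EEF1D (0.14), TPT1 (0.087), NKG7 (1.01), LAMP2 (0.36), SQSTM1 (0.37), PSMD11 (0.20), PSMB2 (0.46), PGK1 (0.18), UQCRFS1 (0.034), MT-ND4 (0.089), SELENOT (0.19), SELENOH (0.23) and CD3D (0.63), by its construction. A filter of 30 reads left 1100 higher genes and gave myeloid differentiation genes an excess of -0.46 (adjusted p = 0.0274), interferon-stimulated genes -0.064 and autophagy genes -0.14, and no filter gave glycolysis 0.031. With intronic reads 2394 genes were lower, MT-ND4 was at 0.041, NKG7 at 0.81 and SP100 at -0.25, and the excess was 0.88 (adjusted p = 0.000633) for ribosomal proteins, 0.69 (0.00163) for 5' TOP mRNAs, 0.72 (0.00903) for glycolysis, 1.29 (0.000633) for mitochondrial mRNAs, 0.23 (0.0707) for respiratory subunits, 0.089 (0.658) for leukaemia-promoting regulators -0.51 (0.0589) for nuclear-retained RNAs, 0.23 (0.326) for myeloid genes, 0.26 (0.658) for blood lineage markers, -0.010 (0.956) for autophagy and 0.36 (0.0589) for proteasome subunits. With coding and 3'UTR reads only, mitotic genes had 0.32 (0.0592). Without matching, architecture factors had 0.40 (0.057) and mitotic genes 0.35 (0.0638). Leaving out 1 IP gave respiratory subunits an excess of -0.37 to -0.26, autophagy -0.25 to 0.10, proteasome subunits -0.14 to 0.035 and glycolysis -0.20 to 0.10.

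Without the 1% of genes with most input reads, the IP to input ratio was 3.07 for coding sequence, 1.31 for intergenic reads, 1.52 for non-coding exons, which turned its direction, and 0.664 for non-coding introns. Without mitochondrially encoded genes it was 0.706 for non-coding exons. Stricter thresholds left 2956 and 1461 significant peaks and looser ones 42261 and 14928. Requiring 50% overlap gave 19.7% and 31.3% shared, the stricter thresholds 19.2% and 31.8%, and overlap on either strand gave identical values and so tested nothing. The upper 50% of the reproducible list by p held 798 peaks. The correlation of the replicates was 0.823 and 0.854 with prior counts of 0.5 and 5, and 0.880 at 30 reads. Against matched genes the excess of genes with reproducible peaks was 4.50 percentage points for P-body factors (adjusted p = 0.588), 11.3 for tumour suppressors (0.0912), 12.5 for leukaemia-promoting regulators (0.196), 6.35 for mitotic genes (0.415) and -13.1 for ribosomal proteins (0.0038), and, called neither way, -10.5 for 5' TOP mRNAs and -3.70 for glycolysis, where the direction turned. Against all genes with input reads it was 8.97 for architecture factors (0.0199), and turned to 0.40 for autophagy and 1.29 for histone genes. Of the 187 list values under alternatives, 165 kept their direction and their side of the threshold. This number includes 19 values with library-size scaling and 19 with median-of-ratios size factors. A change of scaling shifts a list and its random lists alike, so these could hardly move. It also includes lists that were never called.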

Other observations

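The lists of immediate early genes and selenoproteins, and the tests of these, of mitochondrial tRNAs, of introns and of explanations for the ZNF excess, were chosen only after the gene-level pattern they concern had been seen, while the lists of ZNF genes and mitochondrially encoded mRNAs were planned.

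mRNAs of the immediate early and inflammatory response were recovered with DDX6 more than any of the 19 planned lists by median. Of 58 tested, 45 were higher in the IP and 0 lower (49 and 0 adjusted over the list alone), with a median log2 fold of 1.51 (permutation p = 0.0002, two-sided, the smallest these lists can give). TNF (4.04), IER3 (3.37) and OSM (3.03), a cytokine of the IL-6 family, had the smallest p. The median was 2.74 with library-size scaling, which raised the median gene by 1.24. Reproducible peaks were present in 21 of the 58 genes (36.2%) against 3.83% of the other tested genes (two-sided Fisher's exact p = 2.43e-15). Neither this background nor that of the Fisher's exact test below was matched on input reads. Such matching ended the peak calls of several planned lists, and its result for the immediate early list is not reported here. Part of this list had been picked because its members led the table, so the same test was run on the 38 members whose values had not been seen. Of these, 26 were higher and 0 lower (29 and 0 adjusted over the list alone), with a median of 1.27 (permutation p = 0.0002), which lay at percentile 100 of the matched lists. They included the transcription factor genes JUNB (1.75) and KLF10 (1.60) and the early response gene IER5 (1.66), and 7 of the 38 (18.4%) had reproducible peaks (two-sided Fisher's exact p = 0.000683). This is consistent with the hypothesis that these mRNAs, which are short-lived in many cells, are associated with DDX6 as a class.

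tRNAs encoded in mitochondrial DNA were higher in the IP for 13 of 15 tested and lower for 0, with a median of 4.02 log2. They took 0.345% and 0.530% of the reads of IP replicate 1 and IP replicate 2 and 0.0102% of the input. MT-TQ (0.19) and MT-TE (0.18), named after their values were seen, did not pass. Mitochondrially encoded mRNAs had a median of -0.35 on the same scale.

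The selenocysteine tRNA SeC-TCA had 1520, 552 and 20 reads in IP replicate 1, IP replicate 2 and the input. It lay 6.998 and 7.44 log2 above the input when scaled to all counted reads. On that scale the median tested gene rose by 1.24 log2, so these values are not comparable with the gene folds of exonic reads. The hypothesis that selenoprotein mRNAs may be recovered alongside this tRNA was not borne out. Of 15 tested, 0 were higher and 5 lower (0 and 6 adjusted over the list alone), with a median of -0.65 at percentile 0.37 of matched lists (permutation p = 0.0076). The lower members were GPX4 (-1.52), SELENOT (-1.05), SELENON (-1.01), SELENOH (-1.01) and SELENOF (-0.65), of which SELENON and SELENOF were named after their values were seen. With library-size scaling the median was 0.58 and SELENOT (0.19) and SELENOH (0.23) turned. DESeq2 called neither of these, and with intronic reads included edgeR did not call GPX4, SELENOT or SELENOH. Library-size scaling also ended the call of GPX4.

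ZNF genes stood 1.11 log2 above matched genes, and the excess was 1.10 in coding regions (215 of 257 higher, 0 lower). Reads shared between the repeated zinc finger coding arrays of related genes could give this, but the 3'UTRs, which lack the arrays, had an excess of 0.9792 (204 genes, percentile 100 of matched lists), and low input counts could too, but the 159 genes with most input reads had an excess of 0.9767. The introns of ZNF genes went the other way, with an excess of -0.11 (percentile 0.41). Their 5'UTRs had one of 0.22 (63 genes, percentile 90.18), which did not stand apart from matched lists. Less unspliced RNA of these genes in the input is argued against as the whole cause, since their intron-to-exon ratio lay just -0.0929 log2 from that of matched genes (percentile 24.9) and the excess over coding genes matched on that ratio and on input reads was 1.086 (310 genes, percentile 100). Base composition was not tested and stays open.

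Introns higher in the IP were mostly in genes with few exonic reads. Of the 235 host genes of called introns, 9.362% had enough exonic reads to be tested, against 95.15% of the 7601 hosts of introns that were lower. An intron is called lower when it has many input reads, which favours expressed hosts. Of the 37 reproducible intron peaks, 45.95% lay in genes with enough exonic reads, against 97.36% of the 1399 in coding sequence and UTRs. Peaks in exons need exonic reads, which favours such genes too. Unspliced host transcripts bound by DDX6 therefore stay open. Short sequences of other RNAs that the alignment placed in introns may be the source too. That predicts a significant peak of under 150 bases in both replicates for most of the 235 introns, and just 10.21% had one. The value fell far short of the prediction but lay just above the limit set for rejecting it. The test therefore left this explanation undecided. The 37 reproducible intron peaks had a median log2 fold of 6.56, and the 1399 in coding sequence and UTRs one of 3.80.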
